A study of Drosophila melanogaster with 3 samples.

How the data were processed

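The series holds 3 single-cell RNA libraries (10x 3' chemistry) from fly ovaries, 1 for each of the groups anterior, middle and posterior. Per the labels, each used a different GAL4 driver to mark cells with GFP (GMR31C09 for anterior, GMR25A11 for middle, GMR71E07 for posterior). Flies were kept at 25 °C for 5 days, ovaries were dissociated with type II collagenase, mature eggs were filtered out, and live single GFP-positive cells were sorted. The deposited matrices hold counts, whole-number UMI counts per gene and cell barcode, with no normalization. The submitters' processing notes name Cell Ranger 2.1.1, STAR and the genome build dm6. The annotation release and the filter on barcodes are not given in the sources used here. Gene symbols are those of the deposited feature tables (17559 genes, of which 17253 IDs are in the reference annotation used for locations).

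The matrices hold 631 anterior, 1411 middle and 2592 posterior barcodes with 37290446, 51226333 and 73489121 UMIs. Median UMIs per cell were 42494, 26860.0 and 24867, median genes 3917, 3506 and 2825, and the median mitochondrial share 1.96%, 2.61% and 2.21%. Cells with 500 or more genes and at most 20% mitochondrial UMIs were kept, which removed 1 posterior barcode and left 4633 cells. Counts were scaled to 10000 per cell and log transformed. Cells of the 3 libraries were clustered together without integration on 2000 variable genes, 30 components and 15 neighbours with the Leiden method at resolution 0.8, giving 21 clusters. Doublets were kept in the main analysis. Scrublet's own threshold called 4, 4 and 3 cells, and an alternative removed the 3, 16 and 54 cells with the highest scores, a rate of 0.8% per 1000 cells.

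Before the data were examined, 10 marker lists (escort, cap and terminal filament, early follicle, late follicle, germline, muscle sheath, hemocyte, fat body, trachea, neuron), the 18 gene lists, the comparisons, the rule for named genes and the first set of alternatives below were fixed. Clusters were named from the marker lists. A name needed 3 or more markers at 3-fold or more over the other cells (with 10 CPM added to both) and at 100 CPM or more, the most of any type without a tie. It also needed at least 1 marker among the top 10 genes by fold with no other type holding more there. This rule was set after the clusters were seen. It named cluster 6 escort-like, clusters 10 and 11 germline-like and clusters 0, 12 and 15 late follicle-like. Cluster 2, unnamed and led by GstE14, Obp99a and CG43156, served as the class beside which background levels are given, a choice made after seeing the data.

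Raw counts of escort-like cells were summed per library and given as CPM (counts scaled to a sum of 1e+06 UMIs) with exact Poisson intervals. Ratios of CPM carry exact conditional binomial intervals and shares of cells Clopper-Pearson intervals, at 95%, and cover counting error only. Cells are not replicates, and with 1 library per group no test was made. Where a gene had no UMI in a library, the ratio was computed against a floor of 3 counts per library (5.32, 3.44 and 45.7 CPM for anterior, middle and posterior), also inside the medians of lists. Such ratios are given as "at least" against that floor. They are not bounds of a 95% interval, whose upper limit for no UMI was 6.55, 4.23 and 56.2 CPM. The rule for named genes takes genes with 100 or more UMIs over the compared cells, 50 CPM or more and a UMI in at least 10% of cells in the higher library, without mitochondrial, ribosomal protein, rRNA, tRNA, snoRNA and histone genes, ranked by the interval bound nearest 1, the 12 highest in each direction. From each list it adds the up to 4 members with the bound farthest from 1, and it takes up to 8 graded genes in each direction with 1.5-fold steps. Ribosomal protein genes were recognized only by symbols that start with RpL or RpS, here and in the totals without them, so those under other symbols remain.

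The 18 gene lists were Wnt signalling, Hedgehog signalling, BMP signalling, EGFR signalling, JAK-STAT signalling, Notch signalling, ecdysone response, adhesion, basement membrane, redox, heat shock, immediate early, cell cycle, somatic piRNA pathway, lipid and sterol handling, insulin and TOR, retinoid and steroid-binding transport, and position-linked transcription factors. The median log2 ratio of members with 20 or more UMIs was ranked among 10000 random lists of the same size, matched on expression in 20 bins. Of the list symbols, 6 (5 distinct) matched no gene in the files. The median size of log2 ratios, the number of lists outside the central 95% and the number of named graded genes that keep their order were chosen as summaries after the files were seen. Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs, with 4000 UMIs as an alternative.

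The calculation was checked on simulated data by drawing Poisson counts in which 200 genes were set 2-fold or 4-fold higher in the library named first. These draws leave out the spread between cells, so coverage near 95% follows from the method. They do not measure how precise the ratios of the real cells are. For anterior against posterior, 2-fold changes came out at a median of 1.98, with 93.0% of intervals covering the set value and 91% with a bound above 1. For middle against posterior the values were 1.98, 97.0% and 71%, and for anterior against middle 2.06, 94.0% and 100%. With no change set, 97.0%, 95.4% and 95.0% of intervals covered 1. The escort-like cells had a median of 21026, 14831.5 and 10722 UMIs, and the deepest cell held 7.55%, 3.81% and 23.3% of the class's UMIs, so the posterior values rest on 6 cells.

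The first set of alternatives was no cell filter, a stricter filter (1000 genes, at most 10% mitochondrial), doublets removed, all kept cells in place of escort-like cells, resolutions 0.4 and 1.4, TMM scaling, median-of-ratios scaling, the mean of each cell's CPM, totals without mitochondrial and ribosomal protein genes, thinned cells, other minimums for list members, each library clustered on its own, and a 2-fold step for graded genes. Added after seeing the data were escort-like cells plus cluster 16, leaving out the deepest cell of each library, leaving out cells in which muscle markers hold 0.5% or more of UMIs, and clustering without the 10, 50 or 100 genes that lead the escort-like cluster. Clustering used scanpy 1.11.5, anndata 0.12.19 and igraph 0.11.9, statistics numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 under Python 3.11.15, plots matplotlib 3.10.9, and TMM factors edgeR 4.0.16 under R 4.3.3.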

Results

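The 3 libraries, each made from sorted GFP-positive ovary cells, labelled anterior, middle and posterior, held different mixtures of cell types. Each group is 1 library, so no test was run and no difference can be set against a replicate. Every interval is a 95% interval for counting error only. The GAL4 driver, the sort, the library and the region cannot be told apart.

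Germline-like cells, which carry vas and other germline RNAs, were 38.7% (36.1 to 41.3) of the 1411 kept cells of the middle library, 9.03% (6.91 to 11.5) of 631 anterior cells and 1.27% (0.878 to 1.78) of 2591 posterior cells. Late follicle-like cells, which carry yolk protein and eggshell RNAs, were 19.1% (17.6 to 20.6) of posterior, 1.90% (0.986 to 3.30) of anterior and 1.63% (1.04 to 2.44) of middle cells. Escort-like cells, named for the somatic cells that wrap early germline cysts, were 3.80% (2.45 to 5.61) of anterior, 3.83% (2.89 to 4.96) of middle and 0.232% (0.0850 to 0.503) of posterior cells. The remaining 85.3%, 55.8% and 79.4% of the anterior, middle and posterior cells fell in clusters left unnamed. Genes that lead these clusters can differ between libraries and so move their sizes. Germline-like cells fall in clusters 10 and 11, with 45 and 12 anterior, 359 and 187 middle, and 16 and 17 posterior cells. Over both, vas was at 330, 373 and 298 CPM (anterior, middle, posterior), and within cluster 11 osk, which leads it, was at 209, 133 and 246 CPM. In late follicle-like cells Vm34Ca was at 146934, 154333 and 151707 CPM. Unnamed clusters also carry such RNAs: cluster 19, with 14.3% of posterior cells, held Yp1 at 15201 CPM and Vm34Ca at 80929 CPM, and cluster 14, with 12.5%, held Yp3 at 11233 CPM. Cluster 8, with 2.16%, held Yp2 at 27074 CPM, and cluster 9, with 1.43%, held Cp15 at 309638 CPM, so the named share is not that of all cells with yolk or eggshell RNA. The clustering was not repeated without the genes that lead those classes. With the stricter filter germline-like cells were 24.4% of middle and 0.619% of posterior cells, and at resolution 1.4 they were 2.85% of anterior and 26.9% of middle cells. With no filter, which put back 1 posterior barcode, late follicle-like cells were 31.1% of the posterior library. With each library clustered on its own no middle cluster was named germline-like, and late follicle-like cells were 8.399% of anterior, 6.24% of middle and 5.75% of posterior cells.

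The escort-like cluster is led by CG31676, CG2233, Wnt4, Npc2f, GstS1, shf, Timp, CG14072, E(spl)m2-BFM and hh, several of which differ between the libraries. The cells were therefore also clustered without leading genes, a choice made after seeing the data. Without 10, 50 or 100 of them the escort-like cells numbered 42, 43 and 24 in the anterior, 129, 111 and 55 in the middle and 16, 16 and 4 in the posterior library. Cluster 16, which shares Wnt4, CG2233 and hh and stayed unnamed under a rule set after the clusters were seen, held another 2.85% (1.70 to 4.47), 5.46% (4.33 to 6.77) and 0.386% (0.185 to 0.709) of the cells. At resolution 1.4 the escort-like share was 9.98% in the anterior and 15.5% in the middle library, with 63, 219 and 10 cells. Germline-like cells then numbered 18, 380 and 27 instead of 57, 546 and 33. The gain about matches that loss in number, so the class at that setting appears to hold mostly cells named germline-like in the main analysis. With each library clustered on its own the escort-like share was 13.0% in the middle library, and no posterior cell took the name. The lowest UMI count of any barcode was 15975, 12800 and 7099 in the anterior, middle and posterior library. The escort-like medians were 21026, 14831.5 and 10722, so a cut on UMIs can set these shares.

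**Figure D1:**
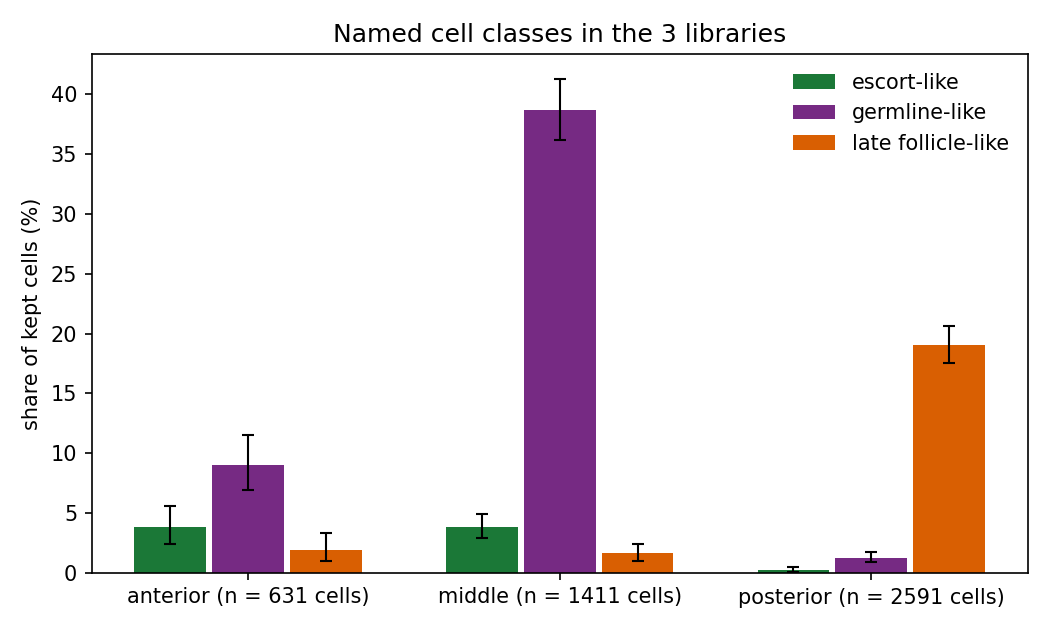
Share of kept cells (%, linear axis from 0) in the 3 named classes for each library; bars are shares and whiskers exact 95% binomial intervals for counting error only. The middle library stands out for germline-like cells (38.7%), the posterior library for late follicle-like cells (19.1%), and escort-like cells are 3.80%, 3.83% and 0.232%.

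Marker RNAs summed over whole libraries, in the order anterior, middle and posterior, are given next. The germline helicase gene vas was at 45.2, 162 and 3.85 CPM, and Vm34Ca, a vitelline membrane protein, at 12208, 12127 and 75167 CPM. The muscle actin gene Act57B was at 30.6, 0.722 and 0.749 CPM, and the early follicle marker Fas3 at 162, 63.4 and 75.3 CPM. The escort marker Wnt4 was at 129.6, 251 and 7.23 CPM. Markers of the same type did not always go together. Of the cap cell list en was at 0.268, 1.29 and 0 CPM and hh, also high in escort-like cells, at 23.1, 37.4 and 0.912 CPM. Of the hemocyte list Hml was at 0.0268, 0 and 0 CPM but crq at 33.2, 43.3 and 34.3 CPM, and of the neuron list nSyb at 0.0804, 0.0781 and 0.0272 CPM but elav at 19.9, 21.3 and 10.1 CPM. The tracheal gene btl was at 0.188, 0.215 and 0.0544 CPM and the fat body gene Mtp at 5.90, 8.59 and 8.70 CPM.

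Escort-like cells of the anterior library (24 cells, 563408 UMIs) were compared with those of the posterior library (6 cells, 65636 UMIs). NLaz (FBgn0053126), a lipocalin, was at 1054 CPM (971 to 1143) in the anterior and had no UMI in the posterior cells (upper limit 56.2 CPM). It was at least 23.1-fold higher against a floor of 3 counts per library. CG14072 (FBgn0032318) was at 1473 CPM against 30.5 CPM, a ratio of 48.3 (13.3 to 399.9, 2 posterior UMIs). CG14984 (FBgn0035480) was at 616 CPM against 15.2 CPM, a ratio of 40.4 (7.21 to 1601, 1 posterior UMI). The Cdc25 phosphatase gene stg (FBgn0003525) was 15.8-fold higher (6.13 to 58.1), and the teneurin gene Ten-a and dysc were at least 7.15-fold and 6.72-fold higher. In the other direction CG2233 (FBgn0029990) was at 5911 CPM (5338 to 6530) in the posterior and 344 CPM (298 to 396) in the anterior cells, 17.2-fold higher (14.4 to 20.5).

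More genes were higher in the posterior escort-like cells. The glutathione S-transferase gene GstS1 (FBgn0010226) was 3.58-fold higher (3.24 to 3.94). For sick it was 4.56-fold (3.19 to 6.44), for Sirup 2.98-fold (2.58 to 3.44) and for Thor, a translation repressor, 3.42-fold (2.53 to 4.59). The ribosome-associated genes sta and Rack1 were 2.34-fold (2.08 to 2.62) and 2.19-fold (1.86 to 2.57) higher. Vm34Ca (FBgn0003983) was 5.21-fold higher (3.64 to 7.39), at 823 against 158 CPM, and cluster 2 of the same libraries, which is not late follicle-like, held it at 564 and 117 CPM. The muscle genes Mf, Mlp60A, Mp20 and Mlc2 had no posterior UMI and were at least 14.1-fold, 10.7-fold, 8.35-fold and 6.91-fold higher in the anterior, where 5, 4, 3 and 7 of the 24 cells held them. Without the 2 anterior cells richest in muscle RNA, Mf stood at about the level of the middle cells (5.73 CPM). That lies under the posterior floor of 45.7 CPM, so its fold rests on those 2 cells.

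Of the 11 measured members of the Wnt signalling list, 7 were at least 2-fold higher in the anterior cells and 0 lower. Their median log2 ratio was 1.80, at percentile 99.99 of 10000 matched random lists (0.088 in cluster 2). Among them Wnt4 was at 2895 against 792 CPM, 3.65-fold (2.77 to 4.91), Wnt6 at least 7.07-fold higher, the receptor gene fz 3.47-fold (1.86 to 7.31) and Notum, a secreted Wnt inhibitor, 11.999-fold (2.11 to 478, 1 posterior UMI). Of 4 measured Hedgehog signalling members 2 were at least 2-fold higher (median 1.61, percentile 99.1). The ligand gene hh was 8.56-fold (3.31 to 31.6) and its receptor gene ptc 1.42-fold higher (1.02 to 2.02). Of 10 Notch signalling members 6 were higher (median 1.06, percentile 99.6), among them E(spl)m3-HLH, 2.15-fold (1.76 to 2.65). Wnt4, Wnt6 and ptc also served to name the escort-like cluster. With fz, Notum, hh and E(spl)m3-HLH they are among 295 escort-led genes, picked as high in middle escort-like cells. Those held a median of 14.0% of UMIs in anterior and 11.6% in posterior escort-like cells. Random lists were matched on expression alone, and anterior cluster 2 held Wnt4 at 1.34 CPM. Neither can tell a difference in these pathways from less escort RNA in the posterior cells. Of 9 heat shock and dissociation stress members 2 were higher and 1 lower (median 0.71, percentile 98.6), with Hsp23 2.53-fold higher (2.005 to 3.23). The other 14 lists lay within the central 95% of random lists. Their median log2 ratios were 0.36 for BMP signalling, 0.65 for EGFR signalling, 0.68 for JAK-STAT signalling, 0.99 for ecdysone response, 0.37 for adhesion, junctions and cell protrusion and 0.48 for basement membrane and matrix. For redox and glutathione it was -0.026, for immediate early and JNK 0.71, for cell cycle -0.35, for the somatic piRNA pathway 0.35, for lipid and sterol handling -0.16, for insulin and TOR -0.063, for retinoid and steroid-binding transport 0.31 and for position-linked transcription factors 0.67. Over the 1036 genes with 100 or more UMIs the median log2 ratio was 0.36 and its median size 0.61, against 0.20 from counting error alone. With far more anterior than posterior UMIs that cut lets in genes high in the anterior more easily, which can lift this median. Scaling by totals without mitochondrial and ribosomal protein genes moved the median of all genes by -0.32 and the Wnt signalling median to 1.21.

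These anterior against posterior values depend in part on which cells count as escort-like. With cluster 16 added 58 of 88 log2 ratios of named genes stayed within the main interval and 12 of 18 list medians within 0.5, and at resolution 1.4 the numbers were 32 and 7. With cluster 16 added, which makes 16 posterior cells, the median of Wnt signalling was 0.85, of Hedgehog signalling 0.089, of Notch signalling 0.54 and of heat shock and dissociation stress 0.11. The log2 ratio of NLaz was then 2.95 instead of 4.53, of CG14072 3.22 instead of 5.595, of stg 1.30 instead of 3.98 and of Wnt4 1.34 instead of 1.87. At resolution 1.4, where the escort-like class appears to hold mostly germline-like cells, the 4 lists had medians of 0.063, -0.26, 0.23 and -0.33. Wnt4 then had a log2 ratio of -0.026, and ptc turned direction. The 19 alternatives overlap. No filter, the stricter filter and doublets removed gave the same numbers of escort-like cells (24, 53 and 4) and UMIs. So did resolution 0.4 and cluster 16 added (42, 131 and 16 cells). TMM and median-of-ratios scaling shift all genes of a library alike, so ranks among random lists could hardly change. Of the 19, Wnt signalling stayed outside the central 95% on the same side in 17 of the 18 that measured it, all but resolution 1.4. Notch signalling did so in 16 of 19, all but resolution 1.4, thinned cells and members at 100 or more UMIs, Hedgehog signalling in 5 of 17 and heat shock in 9 of 19. With no filter, with the stricter filter, with doublets removed and without 100 leading genes, each of which left 4 posterior cells, Hedgehog signalling (median 0.46, percentile 65.6) and heat shock (median 0.34, percentile 85.8) lay within the central 95%. Both lay within it also with cluster 16 added (percentiles 48.3 and 76.5), at resolution 0.4, without 10 or 50 leading genes and over all kept cells. Hedgehog signalling also did without the deepest cell of each library (percentile 97.46), at resolution 1.4 and with members at 1 UMI or more in each library, and at resolution 1.4 heat shock lay outside on the low side. Over all kept cells, a different mix of cell types, GstS1 (1.04), sick (1.62), Sirup (2.35), Thor (0.38), sta (0.11) and Rack1 (0.15) turned direction.

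Middle escort-like cells (54 cells, 872622 UMIs) were set against the same 6 posterior cells, so a gene low there by chance is high in both comparisons. CG14072 was at 1497 CPM (1417 to 1580), a ratio of 49.1 (13.6 to 406, 2 posterior UMIs), NLaz at 395 CPM and at least 8.65-fold higher, and stg 13.1-fold higher (5.09 to 48.2). Hsp23 (FBgn0001224), a small chaperone, was at 5992 against 1143 CPM, 5.24-fold (4.18 to 6.68). Inos, which makes inositol phosphate, was 9.99-fold higher (3.88 to 36.8), Npc2f, of a sterol-binding family, 5.85-fold (3.73 to 9.74), and CG32204, TpnC4, Ten-a and dpr17 at least 5.97-fold, 5.92-fold, 5.49-fold and 4.91-fold. Higher in the posterior were bnb (FBgn0001090), 9.60-fold (6.87 to 13.4) at 990.3 against 103 CPM, sick, 7.20-fold (5.04 to 10.2), wun2, a lipid phosphatase gene, 2.87-fold (2.04 to 3.96), and GstS1, 2.05-fold (1.87 to 2.24). Vm34Ca was 5.52-fold higher (3.94 to 7.64) at 823 against 149 CPM, with 564 and 116 CPM in cluster 2.

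Of 12 measured Wnt signalling members 6 were at least 2-fold higher in the middle cells and 0 lower (median log2 1.08, percentile 99.97, and 0.00020 in cluster 2). Wnt4 was 2.66-fold (2.02 to 3.57), Wnt6 at least 4.99-fold and fz3 5.87-fold higher (1.60 to 48.9, 2 posterior UMIs). Of 11 Notch signalling members 6 were higher (median 1.09, percentile 99.8), among them E(spl)mbeta-HLH, 2.13-fold (1.69 to 2.72). The limit given above for the Wnt and Notch signalling lists holds here too. The 295 escort-led genes, picked in the middle library, held a median of 14.9% of UMIs in middle and 11.6% in posterior escort-like cells. Of 10 heat shock members 6 were higher (median 1.29, percentile 99.99), with Hsp26 3.17-fold (2.74 to 3.70) and Hsp27 3.13-fold (2.51 to 3.97), and in cluster 2 the same list had a median of 0.63. The cell cycle list lay low (13 members, median -0.22, percentile 0.42), although its member stg was higher, and in cluster 2 its median was -0.20. The other 14 lists lay within the central 95%. Their medians were -0.23 for Hedgehog signalling, 0.45 for BMP signalling, 0.37 for EGFR signalling, 0.45 for JAK-STAT signalling, 0.17 for ecdysone response, 0.12 for adhesion, junctions and cell protrusion, 0.35 for basement membrane and matrix and 0.087 for redox and glutathione. For immediate early and JNK the median was 0.97, for the somatic piRNA pathway 0.90, for lipid and sterol handling -0.27, for insulin and TOR -0.32, for retinoid and steroid-binding transport 0.39 and for position-linked transcription factors 0.42. Over 1443 genes with 100 or more UMIs, a cut that genes high in the middle cells pass more easily, the median log2 ratio was 0.33. Its median size was 0.53, against 0.22 from counting error alone. Totals without mitochondrial and ribosomal protein genes moved the median of all genes by -0.27 and median-of-ratios scaling by -0.11.

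The middle against posterior values also depend on the cells taken as escort-like. With cluster 16 added the medians of Wnt signalling, Notch signalling and heat shock and dissociation stress were 0.34, 0.17 and 0.51. The log2 ratio of NLaz was then 1.23 instead of 3.11, of CG14072 2.95 instead of 5.62, of stg 1.18 instead of 3.71, of Hsp23 1.66 instead of 2.39, of Wnt4 0.63 instead of 1.41 and of Vm34Ca -0.83 instead of -2.47. At resolution 1.4, where the escort-like class appears to hold mostly germline-like cells, the Wnt signalling median was -0.042 and the log2 ratio of Wnt4 -0.13. The cell cycle median turned to 0.20 with doublets removed, which left 4 posterior cells. Of the 19 alternatives, which overlap as given above, Wnt signalling stayed outside the central 95% on the same side in 13, Notch signalling in 6 and heat shock in 17. Cell cycle stayed outside it in 6 of the 18 that measured that list. Wnt signalling lay within it with cluster 16 added (percentile 88.9), without 10 leading genes (87.4), in thinned cells (70.6), at both other resolutions and over all kept cells. Notch signalling lay within it with no filter, with the stricter filter and with doublets removed (median 0.58, percentile 93.9), with the mean of each cell's CPM (95.7), with cluster 16 (79.7) and in thinned cells (72.8). It did so too with members at 100 or more UMIs, without 10, 50 or 100 leading genes, at both other resolutions and over all kept cells. Heat shock lay within it only at resolution 1.4 and over all kept cells. The cell cycle list lay within it in 10 alternatives and outside on the high side in 2, over all kept cells and without 10 leading genes. Over all kept cells GstS1 (1.94), sick (0.22), wun2 (0.58) and bnb (0.96) turned direction.

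Anterior and middle escort-like cells, 24 and 54 cells, were compared next. CG2233 was 17.0-fold higher (14.7 to 19.7) in the middle cells, ZnT77C, a zinc transporter gene, 24.2-fold (10.9 to 66.7), CG9360 20.02-fold (7.62 to 74.6), CG12522 10.4-fold (7.02 to 15.9) and TM4SF 7.01-fold (4.43 to 11.7). Higher in the anterior cells were NLaz, 2.67-fold (2.33 to 3.05), the BMP inhibitor gene sog, 3.74-fold (2.51 to 5.68), lea, a receptor for Slit, 2.73-fold (2.02 to 3.70), and the cell adhesion gene Nrg, 2.002-fold (1.67 to 2.41). Zasp66 was 5.23-fold higher (3.73 to 7.47) and CR34335 3.46-fold (3.39 to 3.52), at 60265 against 17444 CPM. Cluster 2 held CR34335 at 14395 and 7758 CPM. Muscle genes and CG7777 were among those farthest from 1 on the anterior side. CG7777, also among the leading genes of clusters 4 and 5, was at 637 against 4.58 CPM (4 middle UMIs). Mlp60A (FBgn0259209) had 275 UMIs in 4 of 24 cells and 0 in the middle cells, at least 142-fold higher. Mf (FBgn0038294) and up, which encodes troponin T, had ratios of 112 (47.6 to 347) and 226 (40.0 to 8992, 1 middle UMI). Without the 2 anterior cells in which muscle markers held 0.5% or more of UMIs, Mf had a log2 ratio of -0.0017 and Mlc2 of -0.85.

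The heat shock and dissociation stress list was lower in the anterior cells. Of its 10 members 2 were at least 2-fold lower, 8 changed less and 0 were at least 2-fold higher (median log2 -0.72, below all 10000 random lists, and -0.33 in cluster 2). Hsp27 was 2.16-fold (2.01 to 2.33) and Hsp23 2.07-fold (1.96 to 2.20) higher in the middle cells. The redox and glutathione list was also lower (18 members, 0 at 2-fold either way, median -0.34, percentile 0.090). GstS1 was 1.75-fold (1.64 to 1.86) and GstE1 1.998-fold (1.60 to 2.51) higher in the middle cells. Hedgehog signalling was higher in the anterior cells (5 members, 0 at 2-fold, median 0.70, percentile 99.5), with ptc 1.67-fold (1.46 to 1.90), hh 1.63-fold (1.38 to 1.92) and the transcription factor gene ci 1.88-fold (1.32 to 2.70). So was Wnt signalling (15 members, 1 at 2-fold, median 0.44, percentile 99.6, and 0.38 in cluster 2), with fz 1.85-fold (1.56 to 2.20) and Wnt4 1.37-fold (1.28 to 1.47). EGFR signalling (14 members, 1 at 2-fold, median 0.39, percentile 99.6) and basement membrane and matrix (10 members, median 0.30, percentile 97.8) were higher too. Of their members aos, an EGFR inhibitor gene, was 4.30-fold (1.94 to 10.5) and the perlecan gene trol 1.39-fold (1.23 to 1.58) higher, while Timp was 1.45-fold (1.38 to 1.53) higher in the middle cells. The other 12 lists lay within the central 95%. Their medians were 0.081 for BMP signalling, 0.33 for JAK-STAT signalling, 0.091 for Notch signalling, 0.25 for ecdysone response, 0.078 for adhesion, junctions and cell protrusion, 0.24 for immediate early and JNK and -0.073 for cell cycle. For the somatic piRNA pathway the median was -0.057, for lipid and sterol handling 0.13, for insulin and TOR 0.12, for retinoid and steroid-binding transport -0.19 and for position-linked transcription factors 0.042. Over 2161 genes the median log2 ratio was -0.037 and its median size 0.26, against 0.12 from counting error alone. At resolution 1.4, where the escort-like class appears to hold mostly germline-like cells, the Hedgehog signalling median was 0.12. Without the 50 leading genes it was 0.14. Of the 19 alternatives, which overlap as given above, heat shock stayed outside the central 95% on the same side in 18, Wnt signalling in 16, Hedgehog and EGFR signalling in 15 each, and basement membrane and matrix and redox and glutathione in 13 each. Over all kept cells each of these except basement membrane and matrix lay within it. Redox and glutathione (percentile 14.6) and basement membrane and matrix (66.2) lay within it with cluster 16 added, as at resolution 0.4, and also without 10 leading genes, in thinned cells and with members at 100 or more UMIs. Basement membrane and matrix did so too without 50 leading genes (97.36). At resolution 1.4 Wnt signalling (97.005), EGFR signalling (84.7) and Hedgehog signalling lay within it. Wnt and EGFR signalling did so in thinned cells, EGFR signalling with members at 100 or more UMIs, and Hedgehog signalling without 10 or 50 leading genes. Over all kept cells NLaz (-0.13), Wnt4 (-0.95), hh (-0.70) and the medians of Wnt signalling (-0.096) and EGFR signalling (-0.18) turned direction.

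**Figure D2:**
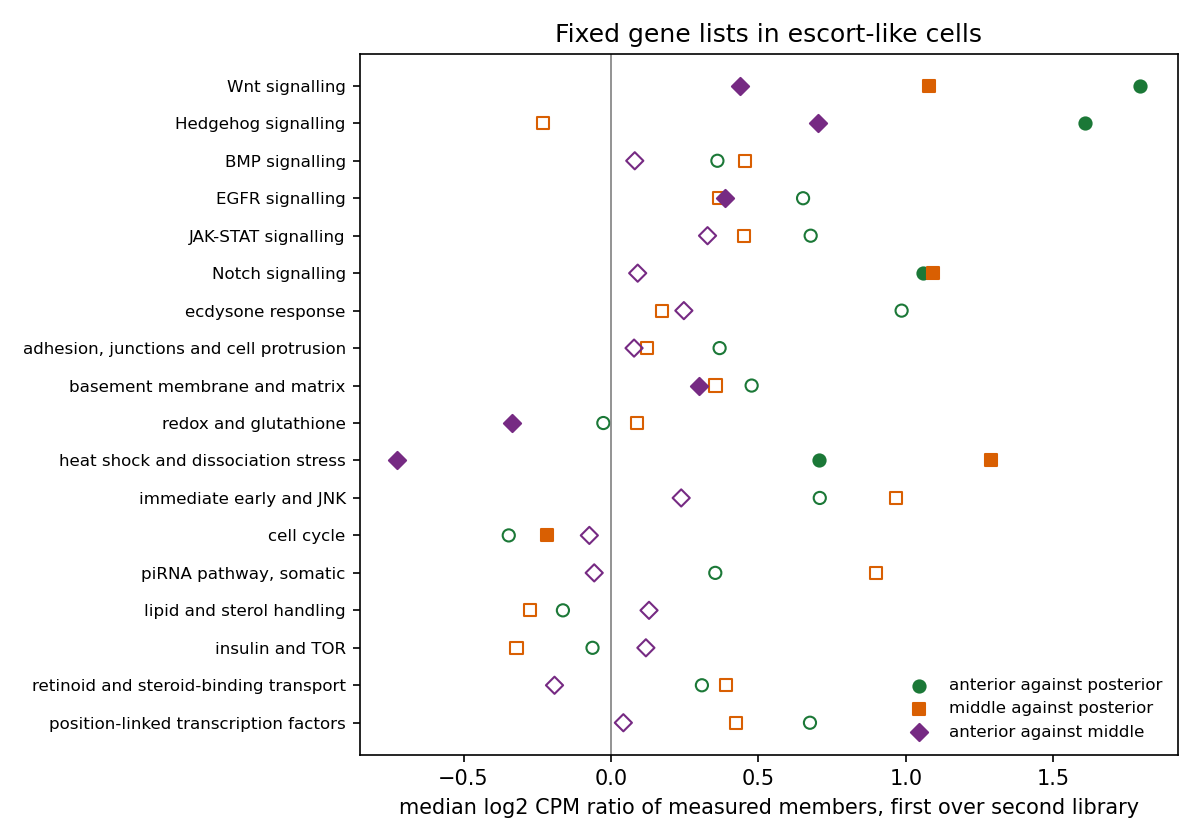
Median log2 CPM ratio (linear axis) of the measured members of 18 fixed gene lists in escort-like cells, for anterior against posterior (circles), middle against posterior (squares) and anterior against middle (diamonds); filled symbols lie outside the central 95% of 10000 matched random lists. Wnt signalling lies to the right in the 3 comparisons (1.80, 1.08 and 0.44), and heat shock lies to the left only for anterior against middle (-0.72).

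Along the order anterior, middle, posterior, 35 genes fell and 4 rose by at least 1.5-fold at each step in escort-like cells, among genes that pass the rule for named genes in anterior against posterior. With 563408 anterior and 65636 posterior UMIs, falling genes pass its cut of 100 UMIs more easily than rising ones. A gene with no posterior UMI was counted against the floor. The 2 numbers therefore cannot be set against each other, and how many such genes counting error alone gives was not computed. The rule names 12 of the graded genes, the 8 falling genes with the interval bound farthest from 1 and the 4 rising ones. NLaz went from 1054 to 395 to 0 CPM, CG14984 from 616 to 178 to 15.2 CPM, the hexosaminidase gene Hexo2 from 886 to 536 to 91.4 CPM, and nrv1, a sodium pump subunit gene, from 422 to 220.0 to 30.5 CPM. CG5210 went from 461 to 258 to 30.5 CPM. The falling genes dysc, glec and SKIP went from 307, 305 and 269.8 CPM to 117, 175 and 109 CPM and had no posterior UMI. GstS1 rose from 2455 to 4285 to 8776 CPM, Thor from 289 to 644 to 990.3 CPM, dUTPase from 197 to 301 to 564 CPM and CG42797 from 137 to 249.8 to 396 CPM. The posterior end rests on 6 cells, whose median depth was 10722 UMIs against 21026 and 14831.5. With a step of at least 2-fold 7 genes fell and 0 rose, 4 of them among the 12 named, and over all kept cells 2 of the 12 named kept the order.

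**Figure D3:**
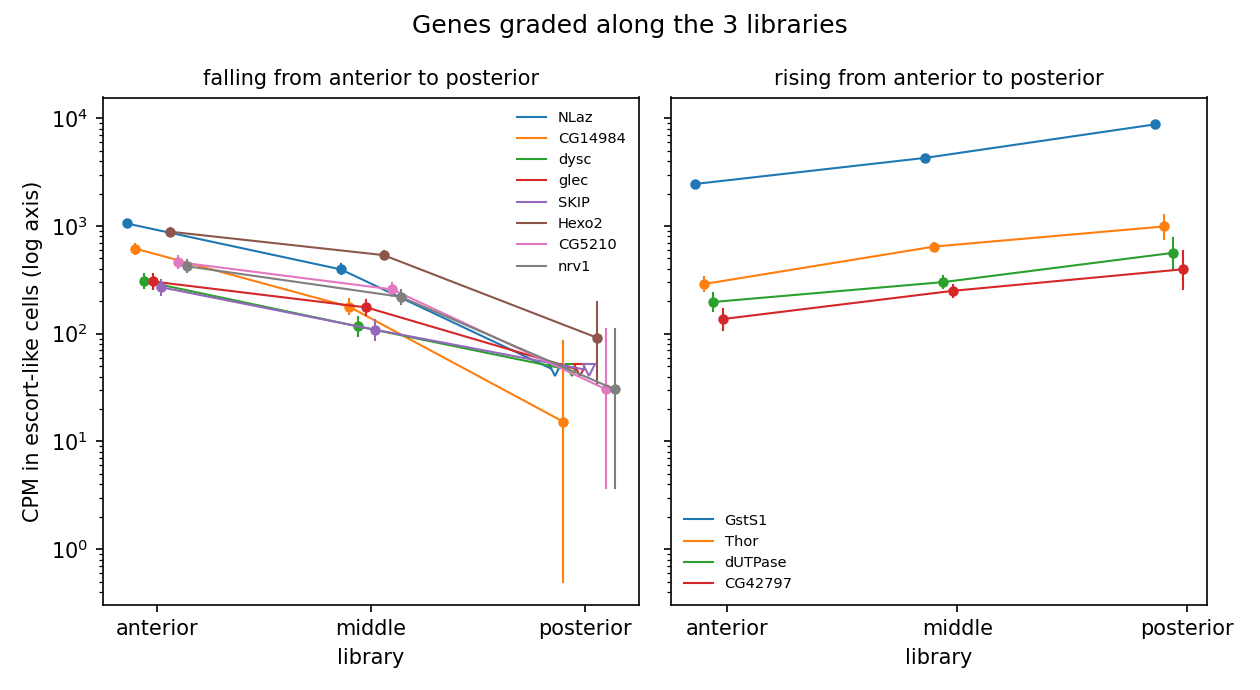
CPM (log axis) of the 12 named graded genes in escort-like cells of the 3 libraries, falling genes on the left and rising genes on the right; whiskers are exact 95% Poisson intervals for counting error only, and open triangles mark genes with no UMI, drawn at the floor of 3 counts. NLaz falls from 1054 to 395 CPM and then to no UMI, and GstS1 rises from 2455 to 8776 CPM.

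With each cell thinned to 2000 UMIs, NLaz was seen in 18 of 24 anterior (interval 53.3% to 90.2%), 40.7% (27.6 to 55.0) of 54 middle and 0 of 6 posterior escort-like cells (upper limit 45.9%), against 100%, 85.2% and 0 unthinned. In cluster 2, whose median depths were 37162, 22706 and 10768 UMIs, the thinned shares were 0, 1.15% and 0.714%. Wnt6 was seen in 45.8% (25.6 to 67.2), 35.2% (22.7 to 49.4) and 0 of the thinned cells, with 0 in cluster 2, and CG14072 in 87.5% (67.6 to 97.3), 87.0% (75.1 to 94.6) and 0, with 1.06%, 1.43% and 0 in cluster 2. For stg the shares were 70.8% (48.9 to 87.4), 59.3% (45.0 to 72.4) and 0, and cluster 2 held it in 28.7%, 26.1% and 22.9% of thinned cells. No escort-like or cluster 2 cell was shallower than 2000 UMIs.

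On the reference annotation of release 6, NLaz lies on chromosome 2L from 1359837 to 1361821, CG14072 on 2L from 10936662 to 10937931, Wnt4 on 2L from 7255419 to 7277171 and Wnt6 on 2L from 7333714 to 7352542. GstS1 lies on 2R from 17093246 to 17099501, CG2233 on X from 8035741 to 8037517, and stg on 3R from 29251826 to 29255800.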

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

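Chosen after the result was seen were the test of free RNA for the germline-like cells, in each of its 3 forms, both tests of muscle RNA, the set of 295 escort-led genes, and the use of cluster 2 as a baseline. The other tests were set before their results were seen. No biological explanation was tested. The position that the labels give was not tested either and cannot be separated from driver, sort and library.

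Germline-like cells of the middle library held escort RNA, a signal outside the compared cells: Wnt4 was at 438.6 CPM, in 93.2% (90.8 to 95.2) of 546 cells (median 29987.5 UMIs), against 6.34 CPM and 14.3% (10.8 to 18.4) of 349 cells in cluster 2 (median 22706 UMIs). The other libraries showed it too. In cluster 11 Wnt4 was at 177, 329 and 217 CPM (anterior, middle, posterior), against 129.6, 251 and 7.23 CPM over the whole libraries. The 295 genes led by the escort-like cluster held a median of 4.62%, 4.49% and 4.73% of UMIs in cluster 11. In cluster 10 they held 4.07%, 4.15% and 3.89%. The tests below cover the middle library only. Other cells here are 734 middle cells outside the escort-like and germline-like classes and cluster 16. Cluster 16 held Wnt4, fax and GstS1 at 436, 600 and 512 CPM in that library, against 438.6, 717 and 540 CPM in germline-like cells. The contrasts were not computed with cluster 16 put back, so leaving it out builds part of each of them in. With that limit, free RNA as the whole source is argued against by the 9 escort markers fixed before the files were seen. They stood at a median of 6.60 times the level of other cells (lower quartile 4.88). Of them 8 lay above 2, with shares apart for the same 8, while tj stood at 1.09. This is the 3rd form of that test and was set with these values known: over 295 genes led by the escort-like cluster a median of 3.71 missed a first bound of 5, a changed bound was met, and both were dropped because those genes were picked to be low in other cells. For chance loading of 2 cells, 97.6% (96.0 to 98.7) of germline-like cells carried the 295 genes at 10% or more of the escort-like share, against a loading rate of 1.13%. The rate was worked out from the 1411 deposited barcodes. A cut on barcodes before deposit would make the rate of the whole library higher. Other cells also passed 1.13% and the bound of 5%, at 21.5% (18.6 to 24.7). Because the 295 genes were picked to be low in other cells, the excess over them is in part built in and decides nothing. The 8 fixed markers with shares apart run from Wnt4, in 93.2% of germline-like and 17.6% (14.9 to 20.5) of other cells, to Stat92E, in 78.4% and 56.3%. They were not picked from these data, but other cells leave out the class named with these markers and cluster 16. Their excess over other cells is therefore in part built in too. Without regard to other cells, each of the 8 was in 56.2% (Wnt2) or more of germline-like cells. That argues against chance loading as the whole source. Whole escort cells or pieces of them attached to germline cells remain a candidate source, as does expression by the germline itself: the log2 ratios of germline-like to escort-like CPM had an interquartile range of 1.13 over the 295 genes, between the 1 that attached cells need and the 2 that would exclude them, and 0.66 over the 9 markers.

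Muscle RNA in anterior escort-like cells is the next pattern. Summed muscle markers stood at 1816 CPM there and 20.8 CPM in cluster 2, a ratio of 87.4 (70.6 to 109), which argues against free RNA. A few cells that hold muscle RNA may account for it: 4 of the 24 cells held 96.1% of the 1023 muscle UMIs. Whether these are doublets, fragments or another cell type stays open.

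Yolk and eggshell RNA was higher in posterior escort-like cells than in those of the other libraries. Free RNA of late follicle cells is consistent with it: over 8 markers, escort-like cells stood a median log2 ratio of 0.12 from the 33 germline-like cells of that library. A doublet with a follicle cell is argued against by the spread of these UMIs, since the cell with most held 23.4% of the 137. The deepest cell held 23.3% of all UMIs, and whether it is the same cell was not checked.

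The anterior values that follow come from cells outside the comparisons and lie above the limit that a count of 0 allows in that library. Cluster 4, led by CG13403, CG7777 and CG10311 and carrying fax, zfh1 and LamC, held 13.0% of anterior cells and 0.0772% of posterior cells. Cluster 5, led by Act57B, sda, CG7777 and Mlp60A, held 22.7% of anterior cells and 0.232% of posterior cells. The RNA of CR34335 was at 14395 CPM in anterior cluster 2 and 4591 CPM in posterior cluster 2.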

How the results depend on the processing

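Tests chosen only after the result was seen are those with cluster 16 added, without the deepest cell of each library, without cells rich in muscle RNA, and clustered without leading genes, and also the summaries and limits by which a value counts as moved. With 1 library per group no paired analysis was possible and no replicate could be left out. A direction counts as turned where the sign changed for a ratio whose main interval leaves out 1 or for a list outside the central 95% in the main analysis. Of 4511 log2 ratios of named genes under alternatives, 3455 stayed within the main interval (3380 keeping their sign), 922 moved (854 keeping their sign) and 134 turned direction, and of 996 list medians 861 stayed within 0.5 (802 keeping their sign), 119 moved (87 keeping their sign) and 16 turned. TMM and median-of-ratios scaling turned none of them. They shift all genes of a library alike, the median log2 ratio by -0.11 to 0.045, so they could turn few. Per-cell scaling and totals without mitochondrial and ribosomal protein genes turned none either. Shares of cells with a UMI stayed within their interval in 180 of 348 cases and moved in 168 when cells were thinned to 4000 UMIs or not thinned. The median size of log2 ratios ranged from 0.36 to 0.74 for anterior against posterior, 0.33 to 0.95 for middle against posterior and 0.19 to 0.40 for anterior against middle. Of the 3 libraries the posterior escort-like cells had the fewest UMIs, with 65636 in 6 cells and a floor of 45.7 CPM. Except for all kept cells, which differ by construction in their mix of cell types, the cause of the changes below was not tested.

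Escort-like shares, for anterior, middle and posterior, were 6.66%, 9.28% and 0.618% at resolution 0.4, 6.66%, 9.14% and 0.618% without the 10 leading genes, and 6.81%, 7.87% and 0.618% without 50. At resolution 1.4 a further cluster of 211 cells took the escort-like name, and germline-like cells fell from 57, 546 and 33 to 18, 380 and 27. That cluster therefore appears to come mostly from cells named germline-like in the main analysis. Escort-like shares were then 9.98% in the anterior and 15.5% in the middle library. With each library clustered on its own they were 13.0% in the middle and 0% in the posterior library. Germline-like shares were 2.85% (anterior) and 26.9% (middle) at resolution 1.4, 24.4% (middle) and 0.619% (posterior) with the stricter filter, and 0% (middle) with each library on its own. Late follicle-like shares of the posterior library were 31.1% with no filter, 26.7% with the stricter filter, 26.6% with doublets removed, 26.2% at resolution 1.4, 26.2% without 10 or 50 leading genes, and 5.75% on its own. On their own the anterior and middle libraries gave 8.399% and 6.24%.

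The median size over expression, anterior against posterior, was 0.36 at resolution 0.4, with cluster 16 added and without 10 or 50 leading genes, and 0.38 at resolution 1.4, against 0.61. For expression, middle against posterior, it was 0.95 over all kept cells and 0.33 at resolution 0.4, with cluster 16 and without 10 leading genes, against 0.53. For expression, anterior against middle, it was 0.40 over all kept cells, against 0.26. Numbers of gene lists outside the central 95%, 4, 4 and 6, became 2, 2 and 2 in thinned cells and 2, 2 and 3 with members at 100 or more UMIs, and 9 for anterior against posterior over all kept cells. Of the 12 named graded genes, 4 kept their order with a 2-fold step, 2 over all kept cells, 7 at resolution 1.4, 3 in thinned cells and 7 without 50 leading genes.

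Turned directions follow as log2 ratios. Over all kept cells, anterior against posterior: Npc2a -0.74, Thor 0.38, eya 1.01, LanB1 0.71, Rack1 0.15, Sirup 2.35, piwi 2.23, dUTPase 1.23, wb 1.81 and tj -1.22. In the same comparison sick 1.62, geminin 1.80, Gadd45 0.33, GstS1 1.04, Egfr -0.22, dally 1.10, fabp 0.014, Inx3 -0.78, sta 0.11 and CG42797 1.90. Middle against posterior: the cell cycle list 2.75, Npc2a -0.47, eya 0.55, santa-maria 0.073, Rack1 0.072, hoip 1.05, piwi 2.98, sick 0.22 and wun2 0.58. There too bic 0.52, GstS1 1.94, GstD3 -0.0044, Inx3 -0.48, kay -0.31, sta 0.22, Gclc 0.096 and bnb 0.96. Anterior against middle: the Wnt signalling list -0.096, the EGFR signalling list -0.18, NLaz -0.13, Thor 0.81, Wnt4 -0.95, Trx-2 -0.22, ab -0.18, bab2 -0.22 and ImpL2 -0.58. Here also vn -0.64, dally 2.0996, CycA -0.58, mirr -0.31, CG45263 0.73, fabp 0.084, GstD1 0.29, Akt1 -0.15, hh -0.70, BM-40-SPARC 0.82 and stg -0.16. For E(spl)m3-HLH, anterior against middle, it was 0.0049, and for N, anterior against middle, 0.31.

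At resolution 1.4, anterior against posterior: the Hedgehog signalling list -0.26, the heat shock and dissociation stress list -0.33, Wnt4 -0.026, dUTPase 0.080, tj -0.57, ptc -0.62, Rho1 -0.25 and bab2 -0.39. At this resolution also dally 0.35, Hsp67Bc -0.23, Hsp26 -0.16, Hsp27 -0.33, mirr -0.38, Timp -0.15, fabp 0.13, Stat92E -0.084 and kay -0.34. Middle against posterior: the Wnt signalling list -0.042, Wnt4 -0.13, Rack1 0.00088, hoip 0.61, kek1 -0.055, Rho1 -0.12 and Notum -0.042. Further values are fabp 0.24, GstD3 -4.62, kay -0.24, Fer2LCH -0.046 and sta 0.052. Anterior against middle: Trx-2 -0.10, RnrL 0.38, ImpL2 -0.68, dally 1.3999, stg -0.22 and kay -0.10.

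At resolution 0.4, as with cluster 16 added, Act42A was 0.18 for anterior against posterior, and for middle against posterior the cell cycle list was 0.44, eya 0.24, kek1 -0.33, fabp 0.13 and kay -0.25. For anterior against middle, Cg25C was -0.060, dally 0.34, BM-40-SPARC 0.052 and Fer2LCH 0.050, and for E(spl)m3-HLH, anterior against middle, it was 0.097. Without 10 leading genes, in the same order, Act42A was 0.18, the cell cycle list 0.48, eya 0.28, kek1 -0.29, fabp 0.10, kay -0.22, Cg25C -0.041, dally 0.32, BM-40-SPARC 0.021, Fer2LCH 0.014 and E(spl)m3-HLH 0.064. Without 50, Act42A was 0.43 (anterior against posterior), the cell cycle list 0.45 (middle against posterior), and dally 0.51 and fabp 0.15 (anterior against middle). Without 100, geminin was 0.58 (anterior against posterior), and the cell cycle list 0.32 and Fas3 0.29 (middle against posterior).

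With no filter, with the stricter filter and with doublets removed, geminin was 0.58 for anterior against posterior and the cell cycle list 0.20 for middle against posterior. With list members at 1 UMI or more in each library, the Hedgehog signalling list was -0.092 for anterior against posterior. In thinned cells tj was -0.15 (anterior against posterior), piwi 0.078 and CR40469 0.070 (middle against posterior), and the basement membrane and matrix list -0.028, Stat92E -0.023 and flam -1.64 (anterior against middle). Without cells rich in muscle RNA, for anterior against middle, Trx-2 was -0.0074, Mf -0.0017 and Mlc2 -0.85.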

Other observations

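Cluster 4, found almost entirely in the anterior library (82 of its cells, 2 middle and 2 posterior), had RNAs of the escort, early follicle and muscle sheath lists. In it fax was at 1056 CPM, zfh1 at 809 CPM and Stat92E at 148 CPM from the escort list, and LamC at 846 CPM, Fas3 at 431 CPM and the zinc finger gene cas at 408 CPM from the early follicle list, while Wnt4 was at 69.5 CPM against 113 CPM in all other cells. From the muscle sheath list sls was at 134 CPM, Mlc2 at 77.5 CPM and Act57B at 67.05 CPM, against 10.3, 7.09 and 6.86 CPM in all other cells. CG7777, at 4204 CPM, and CG13403, at 2846 CPM, led it.

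Cluster 16 (18 anterior, 77 middle and 10 posterior cells) carried Wnt4 at 589, 436 and 479.7 CPM and stg at 637, 661 and 407 CPM, in the order anterior, middle and posterior. Wnt6 was at 50.6 and 59.3 CPM in the anterior and middle cells and had no UMI in the posterior cells (upper limit 22.4 CPM). The germline-like class mixes clusters 10 and 11 differently in each library (45 and 12, 359 and 187, and 16 and 17 cells). Within cluster 10 bam, a regulator of cyst differentiation, was at 95.03, 107 and 119.6 CPM, and within cluster 11 at 13.4, 30.01 and 25.8 CPM.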
